A study of Drosophila melanogaster with 4 samples.

How the data were processed

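Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been done on head nuclei of adult Oregon-R wild-type Drosophila melanogaster with the antibody Q3448 against Su(var)3-7. Per the labels' protocols, heads were sieved from flies of population cages, the tissue was fixed with formaldehyde, and sonicated chromatin was precipitated and washed. The series holds 2 ChIP libraries and 2 input libraries (sonicated chromatin without the antibody step), numbered 1 and 2 in each group. Per the labels, each ChIP library was set against the input of its own number. The labels do not say whether the replicates came from separate cages or collections.

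The files are 3 lists of genomic regions marked as significantly enriched: 1 for each ChIP replicate and 1 for a set that combines the replicates. Each region has a start, an end and a score that the authors deposited; the scale of the score is not given in the sources used here, so scores were used to describe, rank or filter regions within a list, and across lists only as the planned rank correlation. The submitters' processing notes name Bowtie 0.12.7, a short-read aligner. The genome build is FlyBase release 5, per the file headers. The region caller, its threshold, the filters, the treatment of reads that map to several places and the way the replicates were combined are not given in the sources used here. These steps decide how much of a repetitive sequence can be called at all, so covered shares of heterochromatic sequence depend on them. The shortest region was 1301 bp in both replicate lists and 1001 bp in the combined list. The files hold no read counts, so the depth of each library is unknown and no value below carries a depth-based interval. The 2 input libraries have no values of their own here and were not analysed as samples.

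Sequence lengths were taken from the file headers. Across the 3 lists, 1 region began at 0 and 3 ended past the last base of their sequence; these 4 were trimmed to the sequence. The combined list also held 3 regions marked as depleted, which were kept apart. Sequences were grouped as the main arms (2L, 2R, 3L, 3R and X), chromosome 4, the heterochromatic arms (2LHet, 2RHet, 3LHet, 3RHet and XHet), the Y scaffold (YHet) and unplaced scaffolds (U and Uextra). The covered share is the percentage of the bases of a sequence that lie inside enriched regions. Means over the replicates are given with the SD and n = 2, and no test between sequences was run across replicates: an exact two-sided sign-flip permutation test over 2 replicates cannot go below p = 0.5.

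Positions were tested instead. For the overlap of the replicates (at least 1 bp), the regions of one replicate were shifted along each sequence by 1 random distance per sequence, with the end joined to the start, in 100000 draws; this keeps lengths, spacing and the amount per sequence. The same shifts were used for the covered length in the 1 Mb at the centromere end of each main-arm sequence (the end of 2L, 3L and X, the start of 2R and 3R). Such windows are called proximal or next to the centromere below, but they leave out the pericentric sequence listed as heterochromatic arms. How far each arm sequence reaches into heterochromatin is not given in the sources used here. Both tests were one-sided permutation tests whose smallest p is 1e-05. They ask whether positions coincide in these libraries and do not measure variation between flies. Differences of median score between classes of region were tested by a two-sided permutation test over regions with 100000 draws; regions are not independent replicates. Shares of regions carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Benjamini-Hochberg adjustment was applied over the 5 arms within each replicate. The overlap test was tested on simulated main-arm sets that started from 5985 regions with the lengths of replicate 1, placed evenly at random along each arm. A region that ran into the next was cut short there, or dropped if no length was left. The simulated lengths thus fell short of the real ones. Of 40 independent pairs 0 had a p under 0.05 with 2000 shifts. The real regions gathered at several arm ends, so this does not give the error rate for clustered regions. In 5 of 5 pairs 1 set was a random part of the other. There the shift test passed and the copied share was recovered exactly, which that construction makes nearly certain.

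The rule for named regions was fixed before the data were examined, as were the groups of sequences, the tests and most of the alternative settings: the 10 regions with the highest score in the combined list that overlap a region of both replicates, and the 5 longest such regions. Tests on gene starts and on gene lists were not run, because the gene table at hand is of release 6 and coordinates of different releases were not mixed; an annotation of release 5 was not used here. Regions are therefore named by coordinates (release 5, as the files give them). Alternatives covered a stricter score limit, a reciprocal overlap of 50%, merging of regions less than 1 kb apart, other window sizes, random placement in place of shifts, and leaving out each replicate. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.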

Results

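Su(var)3-7 is a zinc-finger protein of heterochromatin, a partner of HP1 and a dose-dependent modifier of position-effect variegation in flies. Its distribution was profiled by ChIP-seq in nuclei from heads of adult wild-type flies, in 2 ChIP replicates each called against its own input. Replicate 1 held 6780 enriched regions that covered 20.0 Mb, and replicate 2 held 6658 regions that covered 21.0 Mb. The mean was 6719 ± 86.3 regions and 20.5 ± 0.727 Mb (SD, n = 2), out of 168.7 Mb of sequence listed in the file headers. Most regions were short: the median length was 2202 bp in replicate 1 and 2190 bp in replicate 2, with the middle 50% between 1888 and 3010 bp and between 1860 and 3116 bp. A small number were long. Regions of at least 10 kb numbered 136 in replicate 1 and 209 in replicate 2, and held 12.4% and 18.1% of the covered length. The combined list held 9474 regions over 29.1 Mb. The lists hold no read counts, so the depth of the libraries is unknown.

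The first comparison asked whether both replicates marked the same places. Of the regions of replicate 1, 5648 of 6780 (83.3%) overlapped a region of replicate 2, and 5403 of 6658 regions of replicate 2 (81.2%) overlapped one of replicate 1. The lists shared 16.3 Mb, which was 66.1% of the 24.7 Mb covered by either. After random shifts the shared length was 3.49 Mb on average and 6.37 Mb at most, so the observed overlap was 4.68 times the shifted mean (one-sided permutation test, p = 1e-05, the smallest the draws can give). Regions found in both replicates had higher scores than the others of their own list, with medians of 0.735 against 0.467 in replicate 1 and 0.691 against 0.553 in replicate 2 (two-sided permutation tests over regions, p = 1e-05 for each). This order held on the main arms, chromosome 4 and the heterochromatic arms in both replicates, but not on unplaced scaffolds in replicate 1, where the medians were 0.938 for shared and 1.17 for other regions. Over the 5648 shared regions of replicate 1, the rank correlation of the authors' scores between the replicates was 0.75 (Spearman's rho, across regions, which are not independent replicates).

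Sharing was uneven between kinds of sequence. On the main arms, 82.6% of the regions of replicate 1 (exact 95% interval 81.7 to 83.6%) and 83.9% of those of replicate 2 (82.9 to 84.9%) were shared, and on chromosome 4 the shares were 81.0% and 80.7%. On the heterochromatic arms 90.6% of the regions of replicate 1 were shared (87.6 to 93.1%), but 61.3% of those of replicate 2 (57.1 to 65.5%). On U, which collects scaffolds without a chromosome, the shares were 89.0% (83.5 to 93.1%) and 60.4% (54.0 to 66.5%). Overlap by chance rises with the covered share, which was 14.2% on the main arms. It was 27.2% on the heterochromatic arms, 44.6% on chromosome 4 and 6.09% on U (means of the replicates). Shifts on the main arms alone left 24.96% of replicate 1 and 25.82% of replicate 2 regions shared. No shifted share was computed for the other classes, so these shares do not rank the classes by reproducibility.

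The second comparison set chromosome arms against each other, since the arms differ in how much heterochromatin they hold. Chromosome 4, a small autosome whose genes lie within heterochromatin-like chromatin, had the highest covered share of the listed sequences in both replicates. Enriched regions covered 44.6% ± 1.78 of chromosome 4 (SD, n = 2), against 14.2% ± 0.00757 of the main arms together, a ratio of 3.15 ± 0.127. The heterochromatic arms, assembled from pericentric sequence, were covered at 27.2% ± 5.92, which was 1.92 ± 0.419 times the main arms. The individual values were 35.2% ± 7.85 for 3LHet, 31.7% ± 5.98 for 2RHet, 28.5% ± 7.84 for 2LHet, 23.9% ± 4.65 for XHet and 13.3% ± 3.69 for 3RHet. Among the main arms, 2R had the highest covered share with 19.2% ± 0.208, followed by X with 15.1% ± 0.545, 3L with 13.5% ± 0.176, 2L with 13.3% ± 0.155 and 3R with 10.9% ± 0.655. The lead of 2R depended on how much of its centromere end was counted. Without the 1 Mb next to the centromere, 2R still led with 16.3% ± 0.00321, against 15.2% ± 0.378 on X. Without the 2 Mb next to the centromere, X stood highest with 15.4% ± 0.328, followed by 2R with 14.2% ± 0.327. The Y scaffold was covered at 2.24% ± 0.155, from 2 regions in replicate 1 and 1 in replicate 2, and U at 6.09% ± 1.83.

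Chromosome 4 and the heterochromatic arms taken as 1 class exceeded the main arms in both replicates; 3RHet alone did not, with 10.7% in replicate 1 and 15.9% in replicate 2. The ratios were 3.06 and 3.24 for chromosome 4, and 1.62 and 2.22 for the heterochromatic arms, in replicates 1 and 2. No test was run across the 2 replicates, since an exact one cannot pass 0.05 with so few. Counted as regions per Mb in place of covered length, the mean ratios over the replicates were 2.24 for chromosome 4 and 1.14 for the heterochromatic arms. The heterochromatic arms thus differed from the main arms more in the length of their regions than in their number. Median lengths differed little in replicate 1, with 2250 bp on the heterochromatic arms and 2201 bp on the main arms. In replicate 2 they were 2773 and 2177 bp. Regions of at least 10 kb held 39.0% and 46.9% of the covered length on the heterochromatic arms, 21.9% and 26.0% on chromosome 4, and 9.18% and 13.7% on the main arms, in replicates 1 and 2. By number of regions the main arms still led, with 88.3% of the regions of replicate 1 (exact 95% interval 87.5 to 89.0%) and 86.0% of those of replicate 2 (85.1 to 86.8%). They make up 70.5% of the listed sequence, or 85.2% without Uextra, a set of unplaced scaffolds on which none of the 3 lists has a region.

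**Figure D1:**
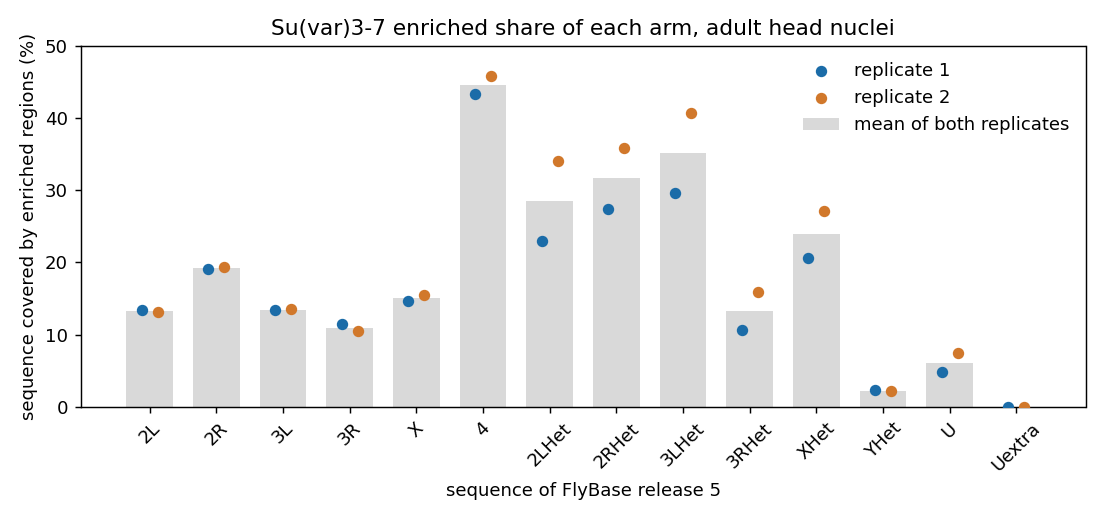
Share of each sequence covered by enriched regions (%, y axis) for the sequences of FlyBase release 5 (x axis). Bars are the means of both replicates and points the replicates; chromosome 4 stands at 44.6% against 10.9 to 19.2% for the main arms, and replicate 2 lies above replicate 1 on all 5 heterochromatic arms.

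The third comparison asked whether the regions on the main arms gathered near the centromeres, where pericentric heterochromatin lies. The 1 Mb at the centromere end of each of the 5 arm sequences is 4.20% of the main-arm sequence in total. It held 12.4% ± 1.71 of the main-arm covered length (SD, n = 2). The shares were 11.2% in replicate 1 (one-sided permutation test by shifts, p = 3e-05) and 13.6% in replicate 2 (p = 1e-05), where shifts gave means of 4.26% and 4.28%. The arms differed widely. On 2R, 77.7% ± 4.45 of the proximal 1 Mb was covered, against 16.3% ± 0.00321 of the rest of the arm. On 2L it was 54.0% ± 6.29 against 11.4% ± 0.448, on 3L 40.7% ± 9.47 against 12.3% ± 0.219, and on 3R 24.0% ± 4.30 against 10.5% ± 0.839. Each of these 4 arms passed the permutation test in both replicates after adjustment over the 5 arms, with the highest adjusted p at 0.036. On X the proximal 1 Mb was covered at 12.7% ± 4.12, against 15.2% ± 0.378 elsewhere, and no excess passed the permutation test (adjusted p = 0.91 in replicate 1 and 0.45 in replicate 2). The windows stop where the arm sequences stop, so this value does not speak for pericentric sequence of X listed apart. XHet was covered at 23.9% ± 4.65.

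**Figure D2:**
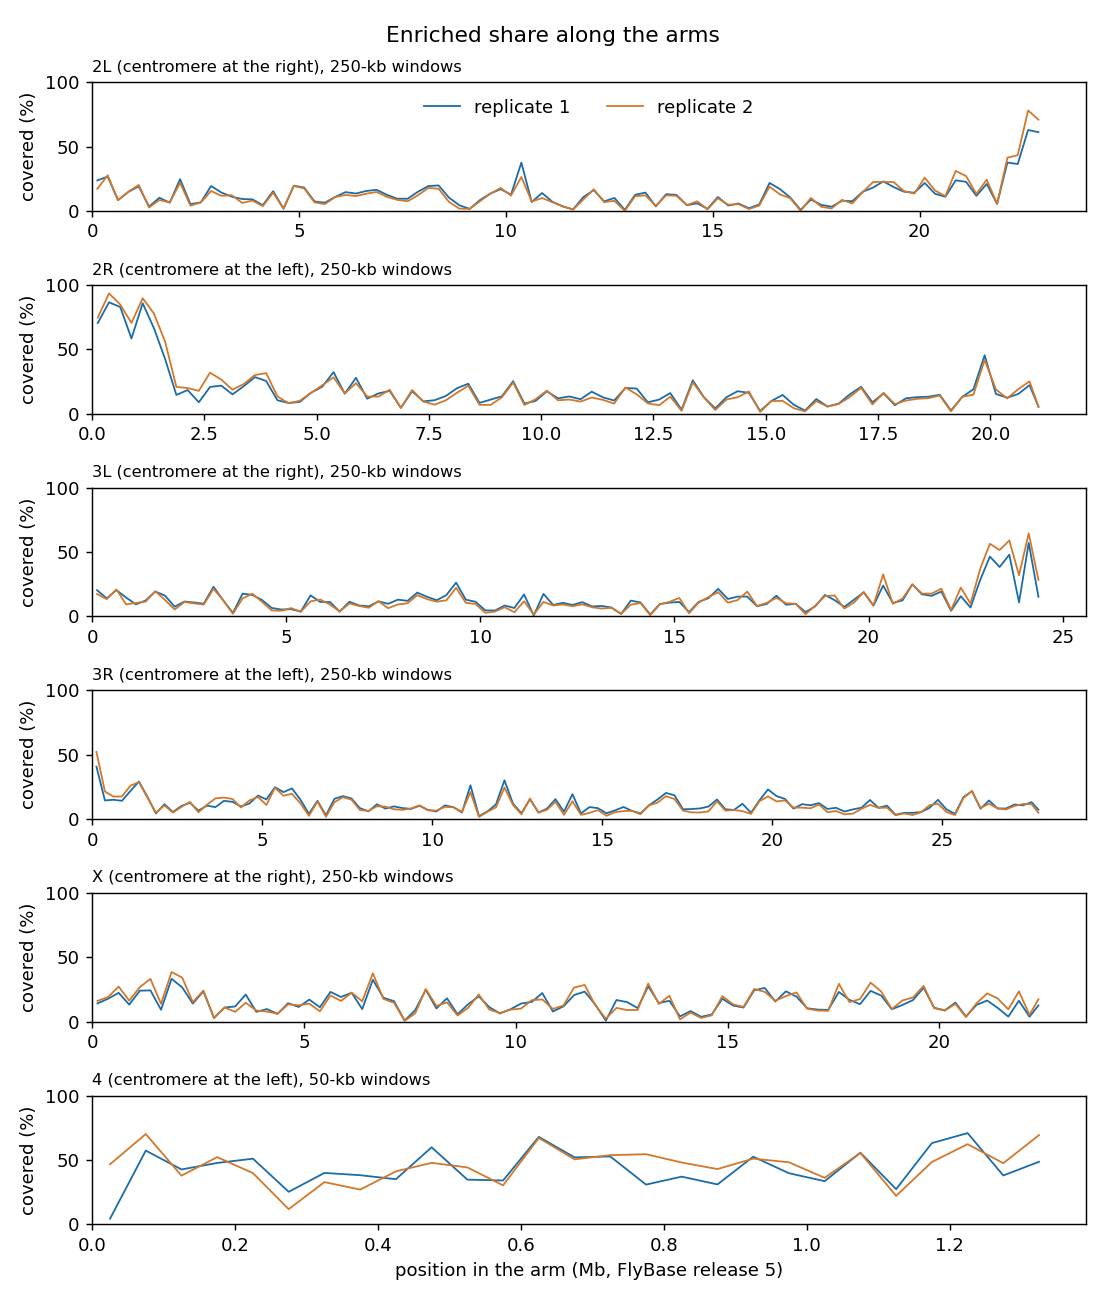
Covered share (%, y axis) in windows of 250 kb along the main arms and of 50 kb along chromosome 4 (x axis, position in Mb), for replicate 1 and replicate 2. Coverage climbs at the centromere end of 2L, 2R and 3L, and within the first 250 kb of 3R, but not on X.

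The regions with the highest scores among those found in both replicates were of ordinary length. The median length was 2907 bp over all combined regions found in both replicates, and 2159 bp over the whole combined list. Of the 10 highest-scoring combined regions found in both replicates, 9 were on main arms, and their lengths ran from 2399 to 3259 bp. The highest score, 3.95, belonged to 3R from 12085163 to 12087925. It was followed by 2R from 11225787 to 11229045 with 3.91, 3L from 3615338 to 3617751 with 3.85, 3L from 2850741 to 2853176 with 3.84, and 3L from 504769 to 507355 with 3.60. The other five ran from 3.54 down to 3.40, and included X from 20630371 to 20632812 with 3.53 and U from 4251781 to 4254179 with 3.40. Each of the 10 met 1 region in each replicate, which covered at least 90.0% of its length. Among the 100 highest-scoring regions found in both replicates, 88 were on the main arms, 10 on U, 1 on chromosome 4 and 1 on a heterochromatic arm, with a median length of 2515 bp. The main arms held 89.3% of the 5043 regions found in both replicates, about their share of the top 100, whereas U held 145 of them (2.88%) and the heterochromatic arms 290 (5.75%).

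The longest regions were pericentric. Of the 5 longest combined regions found in both replicates, 4 lay in the proximal part of 2R and 1 at the far end of 2RHet. They were 2R from 957582 to 1053906 (96.3 kb, score 1.86), 2RHet from 3126683 to 3220716 (94.0 kb, score 1.83), 2R from 1175948 to 1257318 (81.4 kb, score 2.16), 2R from 374638 to 450996 (76.4 kb, score 1.78) and 2R from 1442608 to 1510425 (67.8 kb, score 1.65). Replicate regions covered at least 93.2% of each, in up to 8 pieces. Of the regions of at least 10 kb on the main arms, 62 of 82 in replicate 1 and 88 of 122 in replicate 2 lay in the 2 Mb next to a centromere; in the combined list it was 98 of 163, a lower share.

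The last comparison set the combined list against the replicates from which it was made, so agreement between them is not independent. The combined list took in 99.3% of the regions of replicate 1 and 98.5% of those of replicate 2. Of its 9474 regions, 5043 (53.2%) overlapped both replicates, 1031 (10.9%) replicate 1 alone, 1090 (11.5%) replicate 2 alone and 2310 (24.4%) neither. The regions found in both held 21.6 of the 29.1 Mb, with a median score of 0.66, and those in neither held 3.16 Mb with a median score of 0.374. Regions found in replicate 1 alone had a median score of 0.319, and those in replicate 2 alone 0.386. The share found in both fell from 56.1% on the main arms through 50.7% on chromosome 4 to 37.1% on the heterochromatic arms and 31.4% on U. The shortest region was 1001 bp in the combined list and 1301 bp in each replicate list, though any limit on length is not given. Of the regions found in neither replicate, 54.9% were shorter than 1301 bp.

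**Figure D3:**
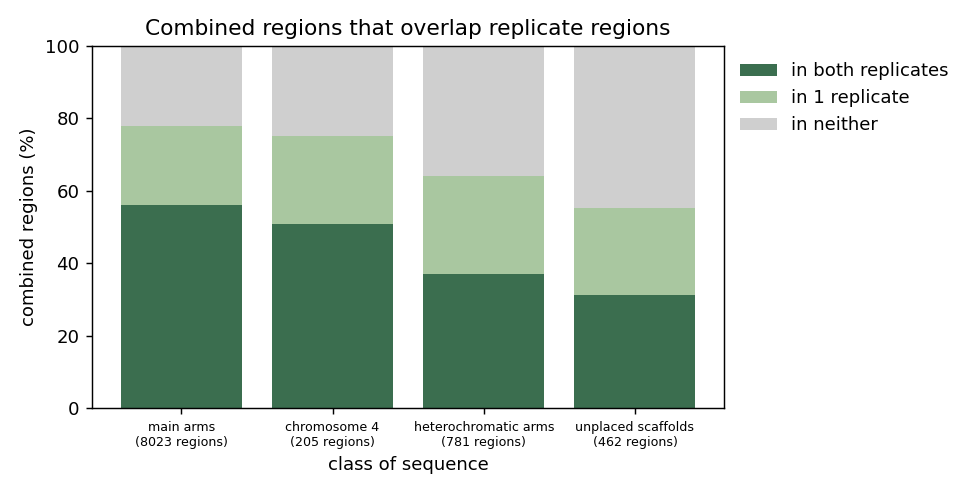
Percentage of the combined regions (y axis) that overlap both replicates, 1 replicate or neither, by class of sequence (x axis, with the number of combined regions). The share in neither is 22.0% on the main arms and 44.8% on unplaced scaffolds; the Y scaffold, with 3 regions, is left out.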

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

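The combined list holds 3 regions marked as depleted, a kind of call that no comparison used; the replicate lists hold regions marked as enriched alone. The depleted regions are 3R from 15860939 to 15862579, 3R from 25314150 to 25316014, and X from 7570347 to 7571942, with scores of -0.0065, -0.015 and -0.043. Of these, the second overlaps an enriched region of each replicate: the lowest-scoring region of replicate 1 (0.026) and one of replicate 2 with a score of 0.162, the ninth lowest there. The third overlaps an enriched region of replicate 1 with a score of 0.195, and the first overlaps none.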

How the results depend on the processing

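No paired analysis was possible because the input libraries have no values of their own here, so the shared replicate numbers join no measured pairs. Of 51 values under other settings, 38 kept their direction and their side of the threshold or, where there was no test, stayed within a fixed limit: the spread between replicates for most values, 1.5 times for numbers of regions and 0.05 for the rank correlation. The number of regions moved by far more than the spread between replicates, to 5665 when neighbours were merged and 5854.5 on the main arms, yet within 1.5 times. For 6 of the 38, untested values with a replicate left out, the limit could not be passed by construction, which leaves 32. The 32 still include the tests near the centromeres with a replicate left out, which only repeat main tests. The other 13 values went past their limit, and none of the 51 turned its direction. Keeping the upper 50% of each list by score left 3359.5 regions on average, a number fixed by construction, and 13.6 of 20.5 Mb. It moved the ratio of chromosome 4 to the main arms to 3.62 and that of the heterochromatic arms to 2.69. The covered length outside the main arms went from 17.8% to 22.6%, and the combined regions found in both replicates from 53.2% to 51.1%. The main arms alone held 16.9 Mb. Counting regions per Mb gave ratios of 2.24 and 1.14, the latter close to 1, so the excess on the heterochromatic arms rests mostly on region length. With the 2 Mb next to the centromeres left out of the main arms, an alternative chosen after seeing the data, the chromosome 4 ratio was 3.63. Requiring replicate regions to cover 50% of a combined region gave 49.1% found in both replicates. Keeping only combined regions of at least 1301 bp, also chosen after seeing the data, gave 63.1%. A reciprocal overlap of 50% raised the rank correlation of scores to 0.82; the cause of this was not tested. Leaving out a replicate gave 3.06 to 3.24 for chromosome 4, 1.62 to 2.22 for the heterochromatic arms, 15.7 to 19.8% outside the main arms, and 11.2 to 13.6% near the centromeres. Sharing between the replicates passed its permutation test (p = 1e-05) under each of the 6 alternatives run for it, including random placement and main arms without the 2 Mb next to the centromeres, with shares from 70.0 to 85.5%. The gathering near the centromeres passed under each of its 7 alternatives. Those that left out a replicate repeat the main test of the other replicate with new draws, so they add no support. The highest p came with 2R left out, chosen after seeing the data (10.3%, permutation p = 0.00037). Other settings for gene starts and gene lists were not run, since those tests were not. Depth is unknown, so a place without a region cannot be told from one too thinly covered to call.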

Other observations

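The windows, contrasts between replicates and tests in this part were chosen after the lists were seen, except the tests of region length and of scores on unplaced scaffolds. In steps of 100 kb, 29 of the 1189 windows on the main arms were at least 50% covered in both replicates. Of these, 28 touched the 2 Mb at the centromere end of their arm sequence. They included 15 windows on proximal 2R, among them 2R from 400001 to 500000 with 98.7% and 98.3% covered, 6 on 2L from 22100001 on, and 7 on 3L between 23100001 and 24200000. None was on 3R or X. The one elsewhere was 2R from 19900001 to 20000000, far out on the arm, with 50.3% and 52.4%. Next among windows away from the centromeres came X from 1900001 to 2000000 with 48.9% and 52.9%, 3R from 12000001 to 12100000 with 55.0% and 47.2%, and 2R from 5400001 to 5500000 with 46.3% and 50.9%. The 3R window also holds the region with the highest score shared by both replicates. Chromosome 4 had 2 of its 13 windows at that level, from 600001 to 700000 and from 1200001 to 1300000.

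Replicate 2 covered more of the heterochromatic arms than replicate 1, while the main arms as a whole were covered alike (14.2% in each). Its covered length was 1.36 times that of replicate 1 on the heterochromatic arms (higher on 5 of 5) and 1.54 times on U, 1.20 times in the 2 Mb next to the main-arm centromeres, 1.06 times on chromosome 4 and 0.952 times on the rest of the main arms. The same regions being called longer is argued against as the whole cause: on the heterochromatic arms and unplaced scaffolds 39.0% of the regions of replicate 2 (307 of 788, exact 95% interval 35.5 to 42.5%) overlap none of replicate 1, against 9.84% the other way. Regions without a counterpart hold 0.633 Mb in replicate 2 and 0.101 Mb in replicate 1, where the net excess of replicate 2 is 1.01 Mb. The excess is larger than the 0.633 Mb, so part of it lies in regions with a counterpart, which covered more in replicate 2. Such regions were fewer in replicate 2 than in replicate 1 (330 against 416 on the heterochromatic arms, 151 against 161 on U). They were thus longer on average, and longer calls make up part of the excess. A laxer call in replicate 2 over the whole genome stays open: it had 0.956 times the number of main-arm regions, but number also falls when neighbours fuse, and away from the centromeres it covered less on 4 of 5 main arms and more on X. A difference between the inputs in heterochromatic reads cannot be told apart from one between the ChIP libraries, because 0 input libraries have values of their own. No biological explanation was tested.

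The region with the highest score in the combined list, 4.86 at 2RHet from 1013112 to 1015118, overlaps no region of either replicate, as do 2 regions on U with scores of 3.24 and 3.13. They belong to the 2310 combined regions without a replicate counterpart. A shorter length limit in the combined list may account for 54.9% of these (exact 95% interval 52.9 to 57.0%), which are shorter than the shortest replicate region, against 2.95% of the other combined regions. The 2.95% is not an independent comparison, since each of those other regions overlaps a replicate region of at least 1301 bp. A shorter limit leaves the 1041 longer regions without a counterpart, the top-scoring region of 2007 bp among them. On the main arms the regions without a counterpart scored lower than those found in both replicates (difference of medians -0.287, permutation p = 1e-05), but their median of 0.354 was above that of regions found in replicate 1 alone (0.315, permutation p = 1e-05) and did not pass the test against those in replicate 2 alone (0.357, permutation p = 0.42), so whether they are weaker places that pass the threshold in the combined call alone stays open. On unplaced scaffolds the difference was -0.0066 (permutation p = 0.93, bootstrap 95% interval -0.206 to 0.160), which leaves it open there too. No biological explanation was tested for this pattern either.

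Uextra, which makes up 29.0 Mb of the listed sequence, holds no region in any of the 3 lists, and whether it was searched is not given in the sources used here.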
